A study of Homo sapiens with 7 samples.

How the data were processed

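Gene expression was measured by RNA sequencing of total RNA from 7 libraries of the lymphoma line SUDHL4, 2 of unedited cells (WT), 2 of clones labelled homozygous for the FOXO1 M1L edit and 3 of clones labelled heterozygous for the S22P edit. The deposited values are counts, raw read counts per gene symbol with 1 column per library. Per the submitters' processing notes, the reads were handled with bcl2fastq, TopHat and HTSeq against hg19/GRCh37. The labels state no versions, annotation or strand setting for these tools, so reads of overlapping or antisense genes cannot be assigned with certainty. The table held 25559 genes.

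Libraries were grouped by the genotype in the labels. Genes were kept by edgeR's filterByExpr with the groups, which left 13110, and libraries were scaled by the trimmed mean of M-values (TMM). All 7 libraries shared 1 fit with a mean per group in edgeR 4.0.16 under R 4.3.3 (robust dispersions and robust quasi-likelihood fit, 4 residual degrees of freedom, common biological coefficient of variation 0.185). The contrasts were M1L against WT, S22P against WT and S22P against M1L, each 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 without a fold threshold. Expression is given in CPM, the standard unit of counts scaled to library size, with TMM-scaled totals, and log2 CPM used a prior count of 2. Total counts were 25012486 to 30513306 per library, at which 3 counts correspond to 0.0987 to 0.12 CPM. A group without counts was given a floor of 3 counts over the group, and ratios with 1 to 3 counts were given with 95% intervals.

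Gene lists were fixed before the data were examined, as were the groups, tests, alternatives and the rule for naming genes. The lists covered FOXO-activated genes, PI3K-AKT components, dark zone and light zone genes, NF-kappaB targets, B cell receptor signalling, MHC class II, MHC class I, plasma cell genes, trafficking receptors, activated B cell type and germinal centre type classifier genes, G1/S and G2/M genes, ribosome biogenesis, cholesterol synthesis, glycolysis, hypoxia, respiratory chain subunits, interferon-stimulated genes, p53 targets, genes downstream of ATF4, the unfolded protein response, heat shock, immediate early genes, the BCL2 family, genes mutated in lymphoma, antibody recombination enzymes, autophagy and lysosome genes, T and NK cell, myeloid and fibroblast, epithelial or endothelial markers, B lineage identity, mitochondrial transcripts, ribosomal proteins and replication-dependent histones. Of 36 lists the 34 with at least 5 tested genes were tested on log2 CPM by camera in limma 3.58.1 with its preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the lists of a comparison. Members were also adjusted over the list alone.

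Named genes were FOXO1, up to 8 called genes per direction and comparison with the largest change, a mean of at least 5 CPM and no overlap between the groups, up to 4 members per list with the smallest p, the largest changes shared by both comparisons with WT, and fixed genes of germinal centre biology. The rule took symbols ending in P and a number as pseudogenes, which would have removed the coding genes DUSP16, FNBP1, PARP9 and SKAP2. Pseudogenes were therefore taken from the reference annotation, a change made after the values were seen. CAND2, CMTM8, ZNF385B, FOXO3B, EHD1 and CIITA fall outside the rule and were chosen after their values were seen. The same holds for the genes of shifted runs and the silent genes SLC16A14, STAT5A, LRP5, PDE9A and SOX2.

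The alternatives were DESeq2's size factors in the same edgeR test, no filter on low counts, the DESeq2 1.42.0 Wald test, a fit with only the libraries of the groups compared, limma-voom, estimated correlation and fry for the lists, and leaving out each library in turn. Leaving out the genes of shifted runs, and leaving out M1L 39 with S22P 10, were added after the data were seen. Calls shared through the common WT libraries were simulated in 100 data sets without group differences. Library pairs were compared by chi-square per degree of freedom over genes with a summed count of at least 20.

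Runs of neighbouring genes were sought after the data were seen. Of the tested genes 92.8% were placed in order by a reference annotation of a later assembly than the one used for the counts, so gene order is used and no coordinates are given. The 8365 placed genes with a mean log2 CPM above 3 were read in windows of 20 genes in steps of 5, against the largest window median of 100 shuffles. Trends over GC content and transcript length were removed by loess with a span of 0.5.

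The test was checked on 5 simulated data sets per comparison with 200 of 13110 genes changed. It recovered 22.4%, 50.1% and 72.7% of genes changed 1.5-fold, 2-fold and 4-fold for M1L against WT, 24.8%, 57% and 78.8% for S22P against WT, and 29%, 55.8% and 81.2% for S22P against M1L. False calls were 10.4%, 7.41% and 6.34% of the calls in that order. Camera with either correlation called a planted list in 5 of 5 data sets per comparison, and the preset test called an unchanged list in 0 of 5. Genes were drawn independently of each other in these data sets. The list check therefore cannot show how often the preset calls unchanged lists whose genes vary together. The run scan found 19 of 20 planted runs of 40 genes at a log2 fall of 0.3 and 20 of 20 at 0.5, with 0 windows elsewhere. Paired tests and splits of the samples into other groups were not made, since replicate numbers are not shared and no comparison has 3 libraries on each side.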

Results

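RNA sequencing measured gene expression in 7 libraries of SUDHL4, an established human cell line of germinal centre type diffuse large B cell lymphoma. FOXO1, the gene edited here, encodes a transcription factor that acts downstream of PI3K and AKT in B cells. The labels name 2 libraries of unedited cells (WT 1 and WT 2), 2 clones with M1L edits in both FOXO1 alleles (M1L 39 and M1L 47) and 3 clones with a heterozygous S22P edit (S22P 10, S22P 29 and S22P 43). Total counts were 25012486 for WT 1, 30269086 for WT 2, 27775314 for M1L 39, 28798462 for M1L 47, 28517053 for S22P 10, 26690954 for S22P 29 and 30513306 for S22P 43, and between 15876 and 16204 of the 25559 genes listed had at least 1 count in a library. The comparisons asked how the transcriptome of each edited genotype differed from that of unedited cells and whether the genotypes differed from each other. The labels do not say whether WT 1 and WT 2 were separate cultures, so the p-values measure only the spread between these samples. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

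FOXO1 was detected in all 7 libraries, from 151 CPM in S22P 10 to 249 CPM in S22P 29 (CPM is the standard unit of counts scaled to library size). Its normalised expression was 160 ± 7.73 CPM in WT (SD, n = 2), 169 ± 8.09 CPM in M1L (SD, n = 2) and 202 ± 49.0 CPM in S22P (SD, n = 3). The log2 fold change was 0.07 (SE 0.21, adjusted p = 0.957) for M1L against WT, 0.33 (SE 0.19, adjusted p = 0.594) for S22P against WT and 0.26 (SE 0.19, adjusted p = 0.808) for S22P against M1L, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A point mutation need not alter the count of its transcript, so these values do not check the edit.

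In the M1L clones, 29 genes fell and 2 rose against WT among 13110 tested. IVD, the mitochondrial isovaleryl-CoA dehydrogenase of leucine breakdown, fell 20.8-fold, from 25.2 ± 0.946 CPM in WT (SD, n = 2) to 1.21 ± 0.0685 CPM in M1L (SD, n = 2). SLC38A5, a plasma membrane transporter of glutamine and other amino acids, had a log2 fold change of -6.74 (SE 0.76), and MCAM, an adhesion molecule of the immunoglobulin superfamily, one of -5.28 (SE 0.61). DUSP16, a phosphatase that inactivates the stress-activated MAP kinases JNK and p38, fell 5.15-fold from 37.8 ± 1.70 CPM (SD, n = 2). TACC1, a coiled-coil protein of the microtubule and centrosome machinery, rose 3.84-fold from 39.1 ± 5.41 CPM (SD, n = 2), and LITAF, a membrane protein of late endosomes and lysosomes, rose by 2.14 on the log2 scale (SE 0.27).

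The other genes named by size in this comparison all fell. They were the ankyrin repeat gene ANKRD33B with a log2 fold change of -3.78 (SE 0.32), the collagen cross-linking enzyme LOXL2 with -2.07 (SE 0.23), LZTS1 with -1.91 (SE 0.23) and the membrane-bending protein FNBP1 with -1.43 (SE 0.16). The adjusted p was 0.0109 for IVD, 0.0281 for ANKRD33B, 0.0387 for DUSP16, 0.0467 for LOXL2 and FNBP1, 0.0474 for SLC38A5, MCAM and TACC1, and 0.0499 for LITAF and LZTS1 (edgeR's quasi-likelihood test, Benjamini-Hochberg over all genes). Of the 31 calls, 28 exceeded a 2-fold change. CMTM8, a tetraspan membrane protein gene, and ZNF385B, a zinc finger gene, were named after their values were seen. Both had no count in either M1L clone, so that CMTM8 was at least 124-fold lower than its WT level of 6.49 ± 0.931 CPM (SD, n = 2) and ZNF385B at least 102-fold lower than 5.34 ± 0.156 CPM (SD, n = 2), with the floor at 3 counts over the group. FOXO3B, also named after its values were seen and also called lower, shares reads with FOXO3, so its count is uncertain.

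These calls rested on few libraries. Without WT 1, without WT 2 or without M1L 47, edgeR called 0 genes in this comparison, with 750, 556 and 1120 genes at an unadjusted p under 0.05 against 1315 in the full data, where DESeq2 called 291 and limma-voom 57. Without M1L 39 it called 11 genes higher and 72 lower, 16 of them among the 31, without S22P 10 8 and 50, without S22P 29 16 and 43, and without S22P 43 0 and 21, of which 15 were among the 31. Where an arm was left with 1 library, that library was assumed to vary like the other groups.

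**Figure D1:**
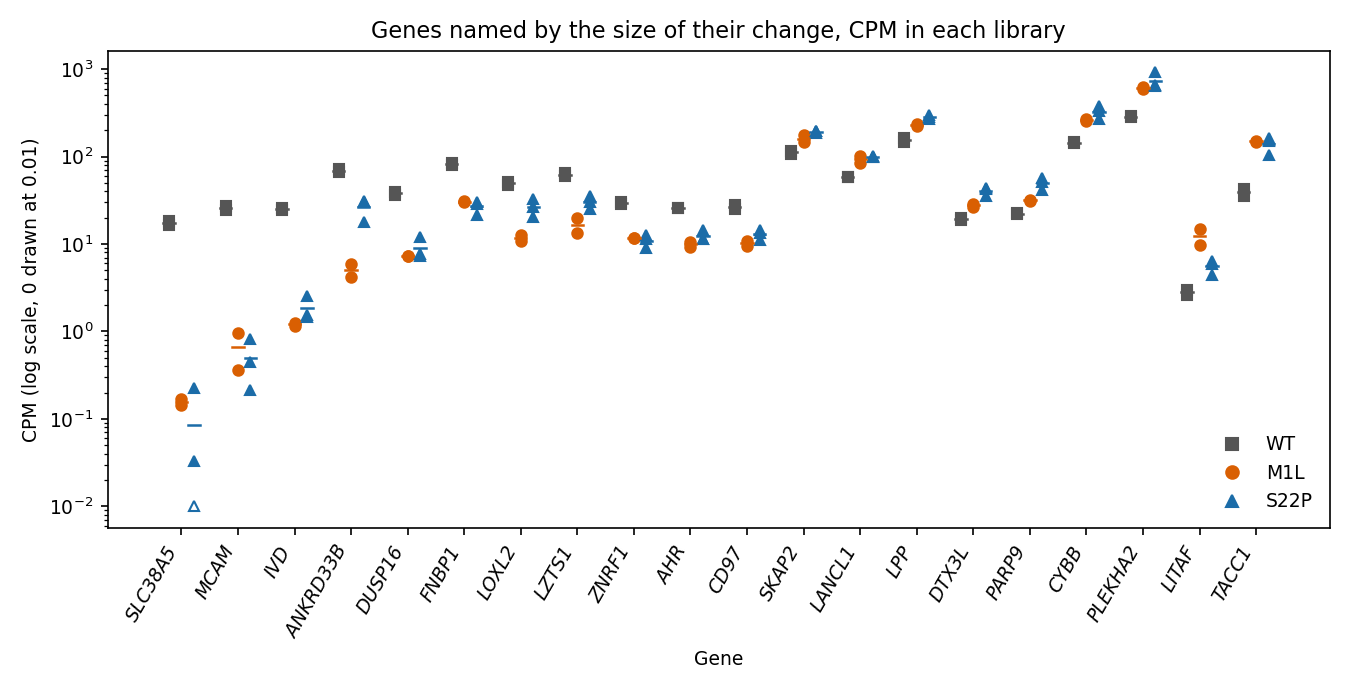
CPM on a log scale (vertical axis) of the 20 genes named by size in the comparisons with WT (horizontal axis), with 1 point per library and a bar at the mean of each group; a library with no count is drawn as an open symbol at 0.01. SLC38A5, MCAM and IVD lay far below WT in all 5 clones, and TACC1 lay above WT in all 5.

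Of 34 gene lists tested in each comparison, camera with its preset correlation called 15 for M1L against WT, 13 for S22P against WT and 15 for S22P against M1L. The genes of MHC class II antigen presentation ranked higher in M1L than in WT with that preset (adjusted p = 2.94e-08), a call that was lost with adjusted p = 0.312 with an estimated correlation. Of 18 measured members 15 had positive log2 fold changes with a median of 0.38, and 13 were higher and 1 lower when adjusted over the list alone, although none passed over all genes. HLA-DRB1 reached 323 ± 32.5 CPM (SD, n = 2) against 216 ± 13.3 CPM in WT (SD, n = 2), a log2 fold change of 0.58 (adjusted p = 0.106), and HLA-DMA, which loads peptides onto class II molecules, had 0.67 (adjusted p = 0.144). HLA-DRB1 and HLA-DRB5 are near-identical over much of their length, so the split of reads between them is uncertain.

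B lineage identity genes were also higher as a group in M1L, with a median of 0.19 over 29 members (adjusted p = 1.63e-05, and adjusted p = 0.312 with an estimated correlation), and 3 members higher and 1 lower when adjusted over the list alone. FCRL1, an Fc receptor-like protein of B cells, had a log2 fold change of 1.61 (adjusted p = 0.162) and POU2AF1, a coactivator of octamer-dependent transcription in B cells, 0.25 (adjusted p = 0.26), while IKZF1, a zinc finger regulator of lymphocyte development, was the member on the lower side with -0.30 (adjusted p = 0.26). The 42 B cell receptor signalling genes had a median of 0.12 with 3 higher and 0 lower adjusted over the list alone (adjusted p = 0.000757, and adjusted p = 0.312 with an estimated correlation). The 24 trafficking receptors had a median of 0.33 with 2 higher and 0 lower adjusted over the list alone (adjusted p = 0.000247, and adjusted p = 0.312 with an estimated correlation). The latter were CXCR5, the receptor that guides B cells into follicles, with 0.83 (adjusted p = 0.0915), and the integrin ITGB1 with 0.40 (adjusted p = 0.141). MHC class I genes had a median of 0.09 over 19 members with 2 higher adjusted over the list alone, HLA-B and HLA-C, which also share reads (camera adjusted p = 0.00895, and adjusted p = 0.635 with an estimated correlation). Without M1L 39 that adjusted p was 0.0557.

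Hypoxia-responsive genes had a median of 0.19 over 22 members in M1L with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000315, and adjusted p = 0.312 with an estimated correlation). BNIP3L, a receptor for the removal of mitochondria, had a log2 fold change of 0.76 (adjusted p = 0.105), whereas P4HA2, a collagen prolyl hydroxylase, fell over all genes (adjusted p = 0.0281). P4HA2 had 2 counts in M1L, and its WT level was 52.8 times the M1L level (95% interval 14.3 to 442). The 27 glycolysis genes had a median of 0.12 (camera adjusted p = 0.000628, and adjusted p = 0.312 with an estimated correlation). Genes of G2 and M phase were positive in 49 of 56 with a median of 0.14 (adjusted p = 9.83e-08, and adjusted p = 0.586 with an estimated correlation). Without M1L 39 that adjusted p was 0.0647. Genes of G1/S and S phase were negative in 38 of 57 with a median of -0.08 (adjusted p = 0.00251, and adjusted p = 0.312 with an estimated correlation). No member of the glycolysis, G2/M or G1/S list passed adjusted over the list alone.

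Ribosomal protein genes were negative in 68 of 77 with a median of -0.08, and RPL8 was lower adjusted over the list alone but not over all genes (camera adjusted p = 7.03e-07, and adjusted p = 0.635 with an estimated correlation). Ribosome biogenesis genes responsive to MYC had a median of -0.07 (adjusted p = 0.0022, and adjusted p = 0.805 with an estimated correlation), cholesterol synthesis genes -0.11 (adjusted p = 0.0233, and adjusted p = 0.805 with an estimated correlation), interferon-stimulated genes 0.34 (adjusted p = 0.0067, and adjusted p = 0.674 with an estimated correlation) and NF-kappaB targets 0.13 (adjusted p = 0.0414, and adjusted p = 0.635 with an estimated correlation). No member of these 4 lists passed adjusted over the list alone. Single libraries ended several of these calls. Without WT 2 the adjusted p was 0.312 for ribosome biogenesis, 0.107 for cholesterol synthesis, 0.0846 for interferon-stimulated genes and 0.0671 for NF-kappaB targets. Without M1L 39 it was 0.0647, 0.304 and 0.291 for the last 3 of these, and without M1L 47 it was 0.429 for ribosome biogenesis and 0.212 for cholesterol synthesis. The NF-kappaB call was also lost without WT 1 (0.0626) and without S22P 43 (0.0505).

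In the S22P clones, 37 genes fell and 13 rose against WT among 13110 tested. IVD fell 13.7-fold to 1.84 ± 0.588 CPM (SD, n = 3) from 25.2 ± 0.946 CPM in WT (SD, n = 2), SLC38A5 had a log2 fold change of -7.63 (SE 0.69), MCAM -5.68 (SE 0.53), DUSP16 fell 4.19-fold and FNBP1 3.04-fold. AHR, the ligand-activated receptor for aryl hydrocarbons, had a log2 fold change of -1.06 (SE 0.14), CD97, an adhesion receptor of leukocytes, -1.02 (SE 0.14) and ZNRF1, a ubiquitin ligase, -1.42 (SE 0.15). TACC1 rose 3.57-fold, PLEKHA2, whose protein binds a phosphoinositide made in PI3K signalling, rose 2.59-fold from 286 ± 6.53 CPM in WT (SD, n = 2), and CYBB, the catalytic subunit of the phagocyte NADPH oxidase, rose 2.25-fold from 145 ± 1.74 CPM in WT (SD, n = 2).

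PARP9 and DTX3L, which encode a partnered ADP-ribosyltransferase and ubiquitin ligase of the interferon response, rose by 1.15 (SE 0.14) and 1.07 (SE 0.12) on the log2 scale. The remaining rises named by size were LPP with 0.87 (SE 0.07), an adaptor of focal adhesions, SKAP2 with 0.79 (SE 0.09), an adaptor of Src family kinase signalling, and LANCL1 with 0.77 (SE 0.08), a glutathione-binding protein. Adjusted p was 0.00886 for IVD, 0.0141 for LPP, 0.018 for SLC38A5 and FNBP1, 0.0192 for MCAM and DUSP16, 0.02 for LANCL1 and ZNRF1, 0.0238 for DTX3L and SKAP2, 0.0322 for TACC1 and PARP9, 0.0362 for PLEKHA2, 0.0413 for CYBB, 0.0416 for AHR and 0.0471 for CD97 (edgeR's quasi-likelihood test, Benjamini-Hochberg over all genes). CMTM8, which had no count in any S22P clone, was at least 184-fold lower than in WT.

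Without WT 1 or without WT 2, edgeR called 0 genes here, with 716 and 778 at an unadjusted p under 0.05 against 1537 in the full data, where DESeq2 called 451 and limma-voom 93. Without S22P 43 it called 10 genes, 6 of them among the 50, and without S22P 29 it called 31, 25 of them among the 50 and 6 of them higher. The number of higher genes was 21 without either M1L clone and 22 without S22P 10, against 13.

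MHC class II genes ranked higher in S22P than in WT with a median of 0.45 (camera adjusted p = 1.17e-11, and adjusted p = 0.349 with an estimated correlation). Of 18 class II genes, HLA-DRB1 and HLA-DRB5 rose over all genes, by 0.70 (SE 0.09, adjusted p = 0.0413) and 0.69 (SE 0.09, adjusted p = 0.0486), and 14 were higher and 0 lower adjusted over the list alone, by edgeR's quasi-likelihood test. CD74, the invariant chain of class II molecules, had 0.31 (adjusted p = 0.0925), HLA-DQB1 0.82 (adjusted p = 0.091) and CIITA, the master regulator of class II transcription, 0.39 (adjusted p = 0.212, named after its values were seen). Of the 29 B lineage identity genes, 16 were higher and 0 lower adjusted over the list alone and 0 over all genes, with a median of 0.37 (camera adjusted p = 1.17e-11, and adjusted p = 0.349 with an estimated correlation). They included PAX5, the factor that commits cells to the B lineage, with 0.64 (adjusted p = 0.0925), the B cell receptor chain CD79B with 0.52 (adjusted p = 0.0966) and FCRL1 with 1.66 (adjusted p = 0.101).

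**Figure D2:**
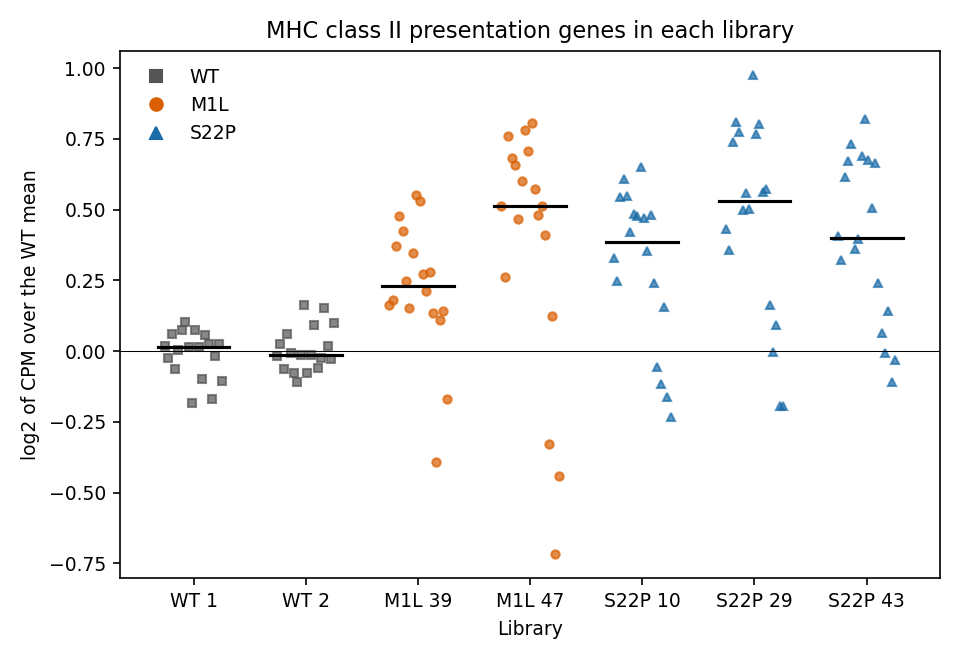
Log2 ratio of CPM to the WT mean (vertical axis) for the 18 genes of the MHC class II list in each of the 7 libraries (horizontal axis), with 1 point per gene and a black bar at the median of the library. The bars of the 5 clones lay between 0.23 and 0.53, and those of WT lay within 0.014 of 0.

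Further lists moved with these in S22P. Some lists share members, such as CD79B and FCRL1 of the B lineage and B cell receptor lists, so the lists are not separate observations. B cell receptor signalling genes had a median of 0.18 with 7 of 42 higher adjusted over the list alone (camera adjusted p = 1.88e-05, and adjusted p = 0.349 with an estimated correlation), MHC class I genes 0.22 with 3 of 19 higher (adjusted p = 1.63e-06, and adjusted p = 0.398 with an estimated correlation) and trafficking receptors 0.30 with 3 of 24 higher, among them CXCR5 with 0.84 and an edgeR adjusted p of 0.0522 (list adjusted p = 0.00128, and adjusted p = 0.349 with an estimated correlation). Interferon-stimulated genes had a median of 0.76 over 29 members with PARP9 and DTX3L higher over all genes and adjusted over the list alone (adjusted p = 1.63e-06, and adjusted p = 0.415 with an estimated correlation). S22P 29 stood apart in this list with a median of 0.975 against 0.277 to 0.39 in the other clones. Endoplasmic reticulum chaperone and unfolded protein response genes had a median of 0.17 over 26 members, none of them passing adjusted over the list alone (adjusted p = 4.47e-04, and adjusted p = 0.495 with an estimated correlation).

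Other list calls in S22P were lost without single libraries. Light zone and activation genes had a median of 0.25 with 2 of 31 higher adjusted over the list alone, CXCR5 and BATF (adjusted p = 0.0143, and adjusted p = 0.619 with an estimated correlation), and NF-kappaB targets 0.15 with 0 of 36 (adjusted p = 0.0218, and adjusted p = 0.538 with an estimated correlation). Without S22P 29 these were lost, with adjusted p = 0.247 and 0.278. Genes often mutated in germinal centre lymphoma had a median of 0.11 with 2 of 29 higher, the adaptor MYD88 and CD79B (adjusted p = 0.0218, and adjusted p = 0.398 with an estimated correlation), and without S22P 29 the adjusted p was 0.0522. Genes of G1/S and S phase had a median of -0.06 (adjusted p = 0.0142, and adjusted p = 0.41 with an estimated correlation), lost without S22P 10 (0.112) and without S22P 43 (0.0542). Ribosomal protein genes had a median of -0.04 (adjusted p = 0.00504, and adjusted p = 0.903 with an estimated correlation), lost without WT 1 (0.506) and without S22P 43 (0.38). Cholesterol synthesis genes had a median of -0.09 (adjusted p = 0.0475, and adjusted p = 0.941 with an estimated correlation), lost without WT 2 (0.207), M1L 39 (0.0705), M1L 47 (0.0706) or S22P 43 (0.118). Without S22P 10 the direction of the cholesterol list turned to higher (adjusted p = 0.897), and its median was -0.42 in S22P 10 and 0.18 in S22P 29.

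The falls in the M1L and S22P clones were largely of the same genes. Both comparisons called 23 genes lower and 1 gene, TACC1, higher, and 0 genes in opposite directions, where independent lists of these sizes would share 0.082 and 0.002. The shared falls included IVD, SLC38A5, MCAM, DUSP16, FNBP1, ZNRF1, AHR, CD97, CMTM8 and EHD1, an ATPase of endocytic recycling. Because both comparisons used the same WT libraries, all 7 libraries, WT included, were simulated without group differences. Genes were drawn independently of each other, each with a spread pooled over the groups. The 2 comparisons then shared 0.13 calls on average and at most 2 in 100 data sets. Across all genes, which are not independent replicates, Pearson's r of the fold changes was 0.732 against a simulated 0.552, and the covariance was 0.296 against 0.105, a difference of 0.191. The simulated r reached at most 0.604. The libraries left after omitting some were simulated likewise, which was added after the results were seen. Without WT 1, r was 0.736 against a simulated mean of 0.753, and without WT 2 it was 0.723 against 0.765. With 1 WT library the simulated spread came from the clones alone. Clones of a genotype differed by a chi-square per degree of freedom of 24.7 to 26.4, and the WT libraries by 5.2. The WT spread was thus set too wide without WT 1 or WT 2, so those comparisons cannot decide whether r showed an excess. In the other simulations the spread was pooled over WT and clones, so the WT spread was too wide there as well. Their simulated r, such as 0.552 in the full data, therefore does not describe the WT libraries' own spread. Pearson's r was 0.539 against at most 0.477 without M1L 39, and 0.57 against at most 0.449 without M1L 39 and S22P 10. On the log2 CPM scale the covariance was 0.239, of which the spread between the WT libraries accounted for 0.0219. A deviation common to both WT libraries would enter both comparisons and was not measured by either estimate. Every clone was edited and no unedited library is labelled a clone. For the shared calls, effects of cloning or culture therefore cannot be told apart from effects of the FOXO1 edits.

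The overlap was 0 without WT 1, WT 2 or M1L 47, each of which left 0 calls in M1L by edgeR, and 7 without S22P 43. By the other tools it was 187 with DESeq2 and 47 with limma-voom.

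**Figure D3:**
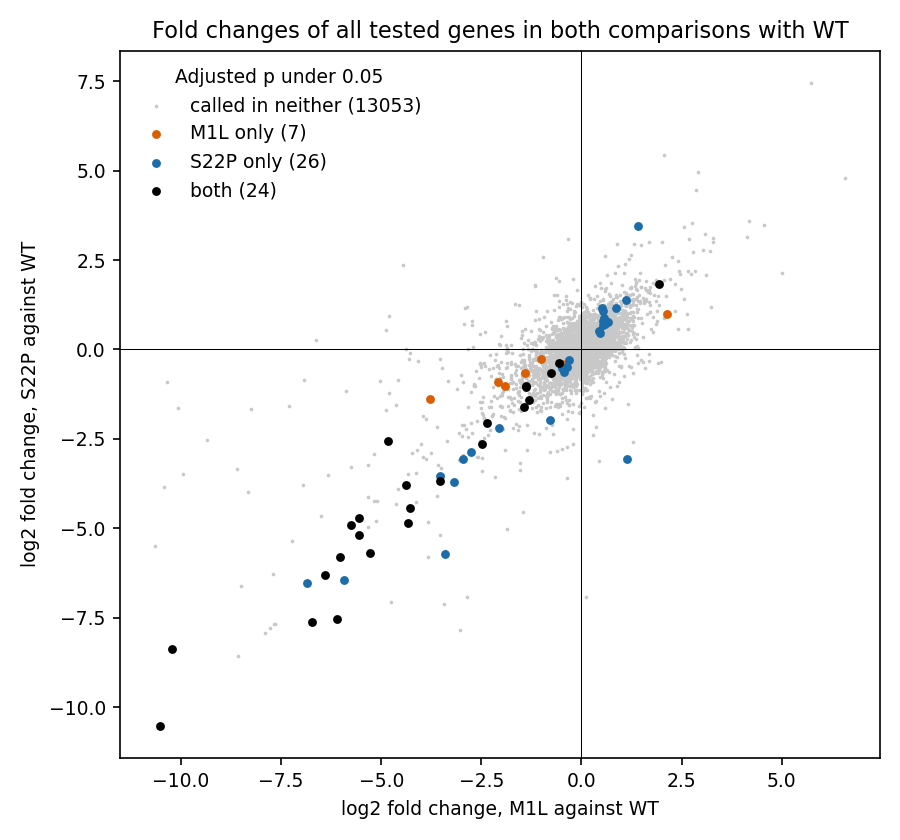
Log2 fold change of each of the 13110 tested genes for M1L against WT (horizontal axis) and S22P against WT (vertical axis), coloured by which comparison called the gene at an adjusted p under 0.05. The 24 genes called in both lie in the lower left and, for TACC1, the upper right; fitted values of genes with no count in a group depend on the prior count.

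The S22P and M1L clones differed from each other in 1 gene called over all 13110. CAND2, a regulator of cullin-RING ubiquitin ligases, was at 0.572 ± 0.165 CPM in S22P (SD, n = 3), 10.6 ± 2.93 CPM in M1L (SD, n = 2) and 4.82 ± 0.135 CPM in WT (SD, n = 2). Its log2 fold change was -4.20 for S22P against M1L (SE 0.29, adjusted p = 0.027), -3.06 for S22P against WT (SE 0.29, adjusted p = 0.018) and 1.14 for M1L against WT (SE 0.29, adjusted p = 0.26), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CAND2 was named after its values were seen. The call was lost without WT 1 and without WT 2, where edgeR called 0 genes with 606 and 594 at an unadjusted p under 0.05, and without S22P 29, where it called 0 with 863. Without M1L 47 and without S22P 43 the 1 gene called was another, and CAND2 had an adjusted p of 0.073 and 0.116. Without M1L 39 edgeR called 74 genes, 68 of them higher in S22P. At an unadjusted p under 0.05 there were 869 genes, where 656 are expected by chance, and DESeq2 called 59 and limma-voom 0 (895 at an unadjusted p under 0.05).

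Between the edited genotypes, the hypoxia and G2/M lists stood lower in S22P than in M1L. Hypoxia-responsive genes had a median of -0.31 with 5 of 22 lower adjusted over the list alone, among them the mitophagy receptors BNIP3 with -0.41 (adjusted p = 0.614) and BNIP3L with -0.56 (adjusted p = 0.614), and 0 over all genes (camera adjusted p = 2.8e-06, and adjusted p = 0.422 with an estimated correlation). G2/M genes were negative in 51 of 56 with a median of -0.12, among them the mitotic kinase AURKA with -0.39 (adjusted p = 0.616), and 0 passed adjusted over the list alone (camera adjusted p = 9.25e-12, and adjusted p = 0.462 with an estimated correlation). Glycolysis genes had a median of -0.13 with 0 of 27 passing adjusted over the list alone (adjusted p = 2.41e-04, and adjusted p = 0.422 with an estimated correlation). None of these 3 calls was lost without any single library.

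B lineage identity genes were higher in S22P than in M1L by a median of 0.10 with 0 of 29 passing adjusted over the list alone (adjusted p = 4.31e-04, and adjusted p = 0.462 with an estimated correlation), without loss on leaving out any library. Interferon-stimulated genes had a median of 0.48 with PARP9 and DTX3L higher adjusted over the list alone (adjusted p = 0.00643, and adjusted p = 0.664 with an estimated correlation), but without S22P 29 the adjusted p was 0.717. Class II genes had a median of 0.08 (adjusted p = 0.0344, and adjusted p = 0.714 with an estimated correlation), with 0.403 without S22P 29 and 0.109 without S22P 43, and without M1L 39 its direction turned to lower (adjusted p = 0.839). Class I genes had a median of 0.13 (adjusted p = 0.0271, and adjusted p = 0.664 with an estimated correlation), with 0.139 without M1L 39, 0.161 without M1L 47, 0.291 without S22P 29 and 0.154 without S22P 43. No class I or class II gene passed adjusted over the list alone.

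The other lists called between S22P and M1L had medians from -0.25 to 0.10. Germinal centre type classifier genes had 0.10 with 1 of 19, LRMP, higher adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.422 with an estimated correlation), lost without M1L 39 (0.166) and S22P 29 (0.1). Ribosome biogenesis genes had 0.07 (adjusted p = 0.0022, and adjusted p = 0.748 with an estimated correlation), lost without M1L 47 (0.483) and S22P 43 (0.317), and ribosomal protein genes 0.03 (adjusted p = 0.0159, and adjusted p = 0.748 with an estimated correlation), lost without M1L 39 (0.166) and S22P 10 (0.613). Unfolded protein response genes had 0.10 (adjusted p = 0.00683, and adjusted p = 0.664 with an estimated correlation) and lymphoma mutation genes 0.06 (adjusted p = 0.0271, and adjusted p = 0.462 with an estimated correlation), lost without M1L 47 (0.155 and 0.406) and S22P 29 (0.304 and 0.196). Autophagy and lysosome genes had -0.07 (adjusted p = 0.0462, and adjusted p = 0.664 with an estimated correlation), lost without WT 1 (0.056), WT 2 (0.0523), M1L 47 (0.41), S22P 10 (0.426) or S22P 43 (0.154). Replication-dependent histone genes had -0.25 (adjusted p = 0.0344, and adjusted p = 0.754 with an estimated correlation), lost without either M1L clone (0.167 and 0.255), S22P 29 (0.717) or S22P 43 (0.168). No member of these last 6 lists passed adjusted over the list alone.

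Genes widely described as activated by FOXO factors were assessed as a fixed list of 38 measured genes, none of which passed over all genes in any comparison. The list's median was 0.23 for M1L against WT (camera adjusted p = 0.00797, and adjusted p = 0.516 with an estimated correlation), 0.00 for S22P against WT (adjusted p = 0.803) and -0.09 for S22P against M1L (adjusted p = 0.00643, and adjusted p = 0.462 with an estimated correlation). Without M1L 47, whose own median was 0.314, the calls were lost with adjusted p = 0.217 and 0.286. Adjusted over the list alone, 0 members passed in the comparisons with WT and 1, BNIP3, was lower in S22P than in M1L. BNIP3 is also a member of the hypoxia list. CDKN1B, the cell cycle inhibitor p27, was at 12.1 ± 0.175 CPM in WT (SD, n = 2), 3.75 ± 2.13 in M1L (SD, n = 2) and 4.71 ± 2.92 in S22P (SD, n = 3), with log2 fold changes against WT of -1.69 (adjusted p = 0.531) and -1.37 (adjusted p = 0.497).

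The other genes chosen for their place in germinal centre biology did not pass in any comparison by edgeR's quasi-likelihood test. For M1L and S22P against WT, the log2 fold changes were -0.14 and -0.06 for the repressor BCL6, -0.37 and -0.19 for MYC, 0.32 and -0.26 for the chemokine receptor CXCR4, 0.10 and 0.23 for CD83, 0.05 and -0.03 for CD86 and -0.07 and -0.17 for the apoptosis activator BCL2L11. CCNG2 had 0.27 and 0.20, TXNIP 0.41 and 0.47, PIK3IP1 0.25 and 0.05 and CCND2, at 1.33 CPM in WT, -0.43 and 0.12. Their adjusted p ranged from 0.398, for CCNG2 in M1L, to 0.946, for PIK3IP1 in S22P. KLF2 had a mean WT level of 0.11 CPM with wide errors, and IRF4, PRDM1 and IRS2 were too low to be tested.

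The 13 lists called in no comparison had camera adjusted p values of 0.116 or more. They were the components of PI3K-AKT signalling, dark zone genes, plasma cell genes, activated B cell type classifier genes, respiratory chain subunits, p53 targets, genes downstream of ATF4, heat shock genes, immediate early genes, the BCL2 family, antibody recombination and hypermutation enzymes, T and NK cell markers and myeloid markers. Over their 924 member tests in the 3 comparisons, 38 passed adjusted over the list alone and 1 over all genes, PIK3R2 of the PI3K-AKT list in S22P against WT with a log2 fold change of -0.51 (edgeR adjusted p = 0.0456). PIK3R2 lies in a run of neighbouring genes that was lower in all 5 clones. The T and NK list had 8 markers high enough to test and the myeloid list 5. Only 4 fibroblast, epithelial or endothelial markers and 0 mitochondrial transcripts could be tested, too few for a list. In every called list the median, the mean and the test had the same sign. No list was called with an estimated correlation or by fry in any comparison, where fry's smallest adjusted p was 0.173, 0.0937 and 0.226 for M1L against WT, S22P against WT and S22P against M1L. Fry's directional p tests whether a list's genes move on balance to 1 side. Its mixed p, which tests change in either direction, called 17, 18 and 3 lists.

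Clones of a genotype differed from each other by about as much as clones differed from WT. The chi-square per degree of freedom between libraries was 5.2 for WT 1 and WT 2, 26.4 for the M1L clones and 24.7 to 25.2 for the S22P clones, against 19.5 to 36.7 between WT and clones. M1L 39 and S22P 10, of different genotype, were the closest clones with 12.6, and r of their deviations from the mean was 0.33 across genes, which are not independent replicates. With both left out, an alternative chosen after seeing the data, edgeR called 65 genes higher and 212 lower in M1L and 121 and 162 in S22P against WT, which included 30 of the 31 and 49 of the 50 genes. It called 84 higher and 18 lower in S22P against M1L, with CAND2 among them.

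Neighbouring genes also shifted together in some clones. In M1L 47 the 163 genes measured on the chromosome that carries FOXO1 had a median log2 difference from WT of -0.52 (95% interval -0.56 to -0.47), 69.6% of the WT level, while FOXO1 itself was at 0.12. The other 4 clones had medians from 0.00 to 0.05 there. M1L 47 also had a run of 40 genes from CAB39 to D2HGDH at -0.52, and S22P 43 had runs of 45 genes from ATAD3B to UBE4B at 0.62 and of 60 genes from POLR3K to AMDHD2 at -0.92. All 5 clones shared a lower run of 135 genes, with medians from -0.28 to -0.21, which held the called genes BABAM1, EPS15L1 and PIK3R2 among others. They also shared a lower run of 45 genes from JRK to ZNF7 and a higher run of 20 genes from RNF5 to HLA-DPB1 that holds HLA-DRB1 and HLA-DRB5. The higher run lies over the class II HLA genes. The 22 genes of other functions among and beside them had a median log2 difference from WT of 0.014. This run therefore does not show a shift of the whole region. With the genes of all runs left out, an alternative chosen after seeing the data, 5 genes were higher and 29 lower in M1L and 18 and 36 in S22P against WT.

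**Figure D4:**
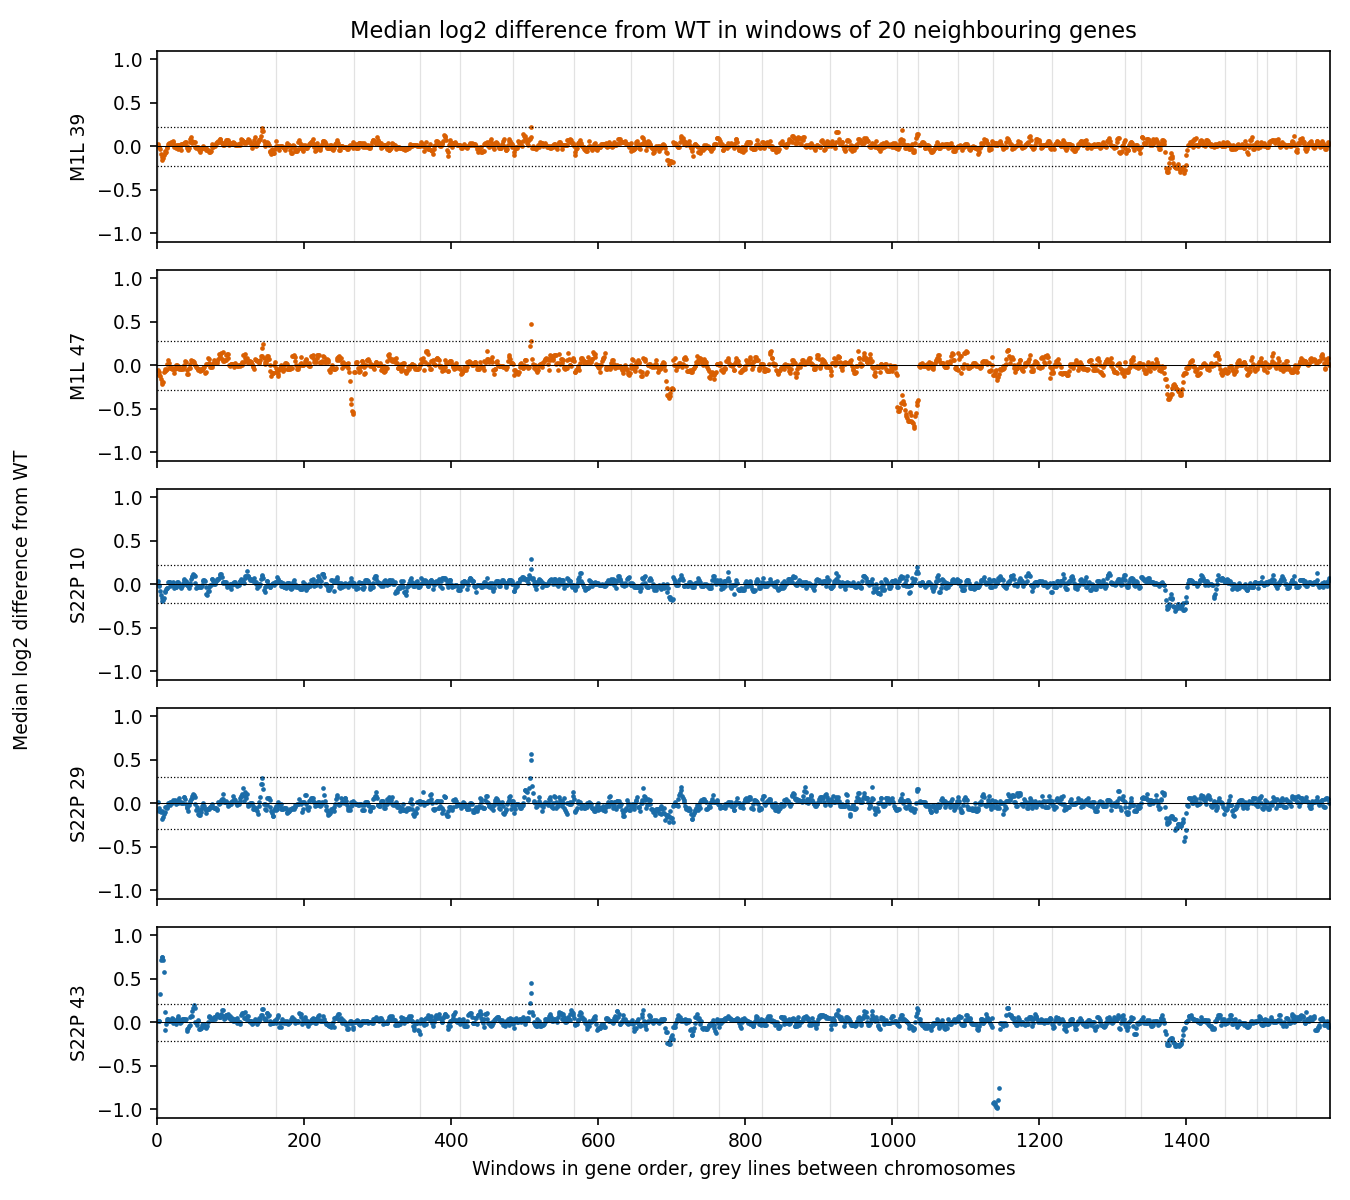
Median log2 difference from the WT mean (vertical axes) in windows of 20 neighbouring genes taken in gene order (horizontal axis), with 1 panel per clone, grey lines between chromosomes and dotted lines at the largest window median of 100 shuffles. M1L 47 and S22P 43 each show runs far beyond the dotted lines that the other clones lack, and the run of 135 genes that holds PIK3R2 is low in all 5.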

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

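The tests of depth, common origin, genotype labels, extra HLA copies, shared HLA reads and cloning were chosen only after the results were seen; those of GC content and copy number were set down before their results.

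CAND2, which encodes a regulator of cullin-RING ubiquitin ligases, differed between the genotypes, with a log2 fold change of -4.20 for S22P against M1L (adjusted p = 0.027 by edgeR's quasi-likelihood test). The difference itself was tested.

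In M1L 47 the chromosome that carries FOXO1, and in M1L 47 and S22P 43 shorter runs of neighbouring genes, lay apart from WT, and a run of 135 genes that holds BABAM1, EPS15L1 and PIK3R2 was lower in all 5 clones. Removing the trends over GC content and transcript length left at least 94.8% of the median in the runs of single clones and 85.9% in the shared run. The less and the more abundant genes of a run shifted together. The smaller shift was at least 71.3% of the median in the runs of single clones and 79.3% in the shared run. The runs were chosen by their medians in these same values, so such a joint shift was likely whatever its cause. It therefore cannot tell a change in DNA copy number, a candidate for both, from another cause acting on a whole run. No DNA was measured, the shared run could equally reflect a gain in the WT cells or a loss before the clones were made, and a biological effect of the edits on the shared run was not tested.

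M1L 39 and S22P 10 resembled each other more than clones of the same genotype did. Library depth is argued against, since M1L 47 and S22P 10, the pair with the closest totals, had a chi-square per degree of freedom of 31.2 against 12.6. A common origin of these clones stays open, since they shared 10 genes silent in them and on in WT, apart from the 3 silent in all 5 clones, but other pairs counted in this way shared up to 11. A wrong genotype label also stays open, since the M1L clones differed by 26.4, within the range of the other clone pairs, and the counts hold no sequence at the edited codons. These explanations cannot be told apart with these data.

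The median of the MHC class II list was above WT in all 5 clones, with 14 of its 18 genes above both WT libraries in each, but its call was lost with an estimated correlation (camera adjusted p = 0.312 for M1L and adjusted p = 0.349 for S22P). Extra copies of the HLA region are argued against by the 22 genes of other functions among and beside them, whose median log2 difference from WT was 0.014. Reads moved between near-identical HLA genes are argued against by the summed class II HLA expression, which was higher by 0.367 or more on the log2 scale in every clone, against 0.039 between the WT libraries. An effect of cloning or culture and an effect of the FOXO1 edits cannot be told apart, since every clone was edited and no unedited library is labelled a clone; the list differed by a median of 0.079 between S22P and M1L clones. An effect of the edits may therefore remain, as an untested explanation.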

How the results depend on the processing

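Leaving out the genes of shifted runs and leaving out M1L 39 with S22P 10 were chosen only after the results were seen. No named gene that passed the threshold under the main or the alternative setting changed sign, whereas some named genes that missed it in both did. The direction of 2 called lists turned, that of cholesterol synthesis for S22P against WT to higher without S22P 10 (adjusted p = 0.897), also when M1L 39 was left out with it, and that of MHC class II for S22P against M1L to lower without M1L 39 (adjusted p = 0.839). The log2 fold change of FOXO1 stayed on its side of the threshold under every alternative that tested it, which leaving out the shifted runs did not since they hold FOXO1, from 0.02 to 0.13 for M1L against WT, 0.15 to 0.51 for S22P against WT and 0.08 to 0.43 for S22P against M1L.

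Genes higher in M1L than in WT numbered 2, and 1 with DESeq2's size factors, 11 without a filter, 109 with DESeq2, 30 with only the groups compared in the fit, 5 with limma-voom, 5 without the runs and 65 without M1L 39 and S22P 10. Genes lower numbered 29, and 47 without a filter, 182 with DESeq2, 90 with only the groups compared, 52 with limma-voom and 212 without M1L 39 and S22P 10. For S22P against WT, 13 genes were higher, and 38 without a filter, 229 with DESeq2, 21 with only the groups compared, 21 with limma-voom and 121 without those clones. There 37 were lower, and 61 without a filter, 222 with DESeq2, 72 with limma-voom and 162 without those clones. For S22P against M1L, 0 genes were higher and 1 lower by edgeR (869 at an unadjusted p under 0.05), and 40 and 19 with DESeq2 and 84 and 18 without those clones. With only the groups compared and with limma-voom 0 were lower, with 580 and 895 at an unadjusted p under 0.05. The overlap of 24 became 41 without a filter, 187 with DESeq2, 47 with limma-voom and 112 without those clones, and r of 0.732 became 0.608, 0.626 and, without those clones, 0.57. DESeq2 called all 31, 50 and 1 of the genes called. With an estimated correlation 0 lists were called in each comparison, against 15, 13 and 15, and with fry 0. Except where fewer libraries or genes were used, the cause was not tested.

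Leaving out 1 library gave 0 to 16 genes higher and 0 to 72 lower in M1L, 0 to 22 and 0 to 49 in S22P against WT, and 0 to 68 and 0 to 6 in S22P against M1L. The overlap ran from 0 to 35, r from 0.539 to 0.736 and the lists called for S22P against M1L from 9 to 16. The counts of 0 in both comparisons with WT came without WT 1 and without WT 2, by edgeR, with 750 and 556 genes for M1L and 716 and 778 for S22P at an unadjusted p under 0.05.

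No paired analysis was possible because the groups share no replicate numbers. With 2 WT libraries every comparison with WT rests on the pair, and a clone left alone in its arm was assumed to vary like the other groups. At 25012486 to 30513306 counts per library, a gene under 0.0987 CPM in a library had fewer than 3 counts, so that smaller levels were not measured.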

Other observations

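The silent genes and the FOXO1 chromosome were described only after the results were seen.

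Some genes expressed in WT were silent in 1 or more clones. Of 10321 genes with at least 2 CPM in both WT libraries, 26 were below 0.1 CPM in M1L 39, 38 in M1L 47, 30 in S22P 10, 28 in S22P 29 and 27 in S22P 43. Of the 83 genes silent in any clone, 45 were silent in exactly 1 clone and 3 in all 5, CMTM8, SLC16A14 and ZNF385B. The cutoff of 0.1 CPM is near 3 counts, so a gene silent by it in 1 clone can be near 0 in others. SOX2 was at 0.04 CPM in M1L 39 and at 0.16 to 0.30 CPM in the other clones. Apart from the genes silent in all 5, pairs of clones shared 5 to 11 silent genes, where 0.053 to 0.092 would be expected for independent lists. That expectation takes every gene on in WT as equally likely to fall silent, whatever its WT level. All pairs were also set against the same WT libraries, so the excess does not measure how closely clones are related. STAT5A, a transcription factor of cytokine signalling, had 25.4 and 19.4 CPM in WT and 0.07 CPM in M1L 47, but 31.4 CPM in M1L 39 and 34.2 CPM in S22P 10. LRP5, a co-receptor for Wnt ligands, had 28.0 and 32.3 CPM in WT and no count in S22P 29 and S22P 43, but 29.5 CPM in S22P 10. PDE9A, a phosphodiesterase that degrades cyclic GMP, had 14.5 and 16.3 CPM in WT, no count in M1L 39 and S22P 10, and 30.6 CPM in S22P 29.

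FOXO1 itself was not lower than WT in M1L 47, where its chromosome was. Of 163 genes measured there, 92% lay below both WT libraries, with medians of -0.46 over the 56 genes before FOXO1 and -0.55 over the 106 after it. FOXO1 itself was at 0.12 in M1L 47. In the other clones, with chromosome medians from 0.00 to 0.05, FOXO1 ranged from -0.08 in S22P 10 to 0.64 in S22P 29. With that spread, the value in M1L 47 cannot show whether FOXO1 was exempt from the shift of its chromosome.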
